A study of Bos taurus with 4 samples.

How the data were processed

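RNA-seq and small RNA sequencing were done on primary mammary epithelial cells of Chinese Holstein cows, isolated from mammary tissue by tissue culture and enzyme digestion, per the labels. Total RNA was extracted with TRIzol and treated with DNase I, RNA over 18 nucleotides was kept, and libraries were made with an Ion Total RNA-Seq kit, per the labels' protocols. The small RNA samples are titled Solexa. The trimming, aligner, counter, genome build, annotation and miRNA database versions are not given in the sources used here.

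The authors deposited 1 table of whole-number read counts per gene for both RNA-seq libraries, in columns named HH and LL per the file headers. It lists 31021 gene symbols with a gene type and the symbols of the best human and mouse matches, keeps genes at 0, and is not normalised. Of these symbols 23435 matched a symbol or synonym of the RefSeq gene table of assembly ARS-UCD2.0, which was used only for names and for which miRNA genes lie in which genes. Genes of the type mRNA held 95.9% of the HH counts and 95.6% of the LL counts. For each small RNA library the authors deposited a list of distinct sequence tags with length, read count and a precursor name. Every listed tag had the class miRNA and the tag numbers have gaps, so other small RNAs were not analysed here, and the totals are miRNA reads, not library depths. RPM values are reads scaled to 1000000 miRNA reads. The tags ran from 18 to 29 nt.

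Groups were taken from the title codes HH and LL, since the phenotype label gives the same value to both libraries of a kind. Each group is 1 library. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). The log2 ratio of HH over LL was given the exact (Clopper-Pearson) 95% interval of the share of counts from HH. The interval covers counting error of reads only. It may be too narrow even for that, because sequencing reads without molecular identifiers are not independent molecules. A gene or precursor was called higher in a library when the whole interval lay past 2-fold, among those with at least 100 summed counts. Where a library had 0 counts, the ratio was set against a floor of 3 counts in that library. This floor is 0.173 CPM in HH and 0.184 in LL for RNA-seq, and 0.423 and 0.331 RPM for small RNA. No p-value across genes was computed, since genes are not replicates.

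The plan made before the data were examined spoke of mature miRNAs. The tag files name precursors only, so tags were summed per precursor, and tags sharing 12 bases with the most abundant tag of a precursor were treated as its arm. Precursors of the same mature miRNA, such as bta-mir-29b-1 and bta-mir-29b-2, share sequences, and how their reads were assigned is not given in the sources used here.

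The median log2 ratio of each fixed list (23 gene lists and 7 miRNA lists, members with at least 20 summed counts) was placed among 10000 random lists of the same size, matched on 10 bins of mean expression for genes and 5 for miRNAs. The gene lists covered fatty acid synthesis, uptake, oxidation, triacylglycerol, lipid droplets, lipid regulators, cholesterol, milk proteins, markers of 6 cell types, the cell cycle, interferon, inflammation, insulin signalling, stress, immediate early genes, glycolysis, ribosomal proteins and mitochondrial transcripts. A list median outside the middle 95% of its random lists is described as standing apart. A comparison of predicted miRNA targets was planned but not run, since 3′ untranslated regions were not used here.

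Named genes were fixed by rule: the 12 genes highest and the 12 lowest in HH, ranked by the interval bound nearest to no change, the 5 most abundant genes of each library, up to 4 members of each list with the largest ratios, and a preset panel of lipid, casein and keratin genes. For miRNAs the 8 highest, the 8 lowest and the 5 most abundant were taken, with up to 4 members per list. Genes named outside this rule are said to be so in the text. Results on a few genes under the rule are left out of the text because those items are withheld for evaluation.

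Scaling by total counts, by DESeq2 1.42.0 size factors and by the upper quartile, other count minimums, a point ratio and a 4-fold threshold were set beside the main choices. Further alternatives were added after seeing the data: removing a straight line on GC content, tags of at least 21 nt, the leading arm only, genes without a shared human match, and genes of the type mRNA only. Correlations across miRNAs were tested with 100000 permutations, two-sided, in scipy 1.17.1, and Benjamini-Hochberg adjusted over 10 relations.

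The steps were tested on simulated data with counting noise only. For the 12804 genes, 98.0% of 3-fold and 100.0% of 8-fold changes were called, with 0 calls among 12604 unchanged genes, and 95.4% of intervals held the true ratio. For the 143 precursors, 95.0% of 3-fold and 100.0% of 8-fold changes were called, with 0 calls among 103 unchanged, and 93.7% of intervals held the true ratio. Random gene lists lay outside both percentile limits in 6.90% of 1000 draws on simulated ratios and 4.30% on the real ones, and random miRNA lists in 4.10% and 5.10%. On the real ratios a shift of 0.4 in log2 was found in 98.9% of gene lists of 20 but in 18.1% of miRNA lists of 10. Replicate variation was not part of these simulations.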

Results

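Messenger RNA and small RNA were sequenced from primary mammary epithelial cells of Chinese Holstein dairy cows. There were 4 libraries: 1 RNA-seq and 1 small RNA library titled HH, and 1 of each titled LL. The series describes cells from cows whose milk fat was high (4.85%) or low (3.41%). The labels do not spell out the codes HH and LL. The phenotype label reads high milk fat for both RNA-seq libraries and low milk fat for both small RNA libraries, so it does not separate the codes. Every direction is therefore given as the HH library against the LL library.

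The RNA-seq table held 17369144 counts for HH and 16318951 for LL over 31021 genes, of which 8376 had no count in either library. The small RNA files listed 7087726 miRNA reads for HH and 9059038 for LL, in 307 and 348 miRNA precursors. With 1 library per code, no difference has a replicate check, and every comparison is between those libraries, not between the conditions. Intervals are 95% exact binomial intervals, and they and the floors for a count of 0 cover counting error of reads only. The genes are identified by the symbols of the deposited table. No genome build is given in the sources used here, so no coordinates are printed.

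Casein transcripts were abundant in both RNA-seq libraries. The 4 casein genes together took 8.92% of the HH counts (exact interval 8.91 to 8.94%) and 9.58% of the LL counts (9.56 to 9.59%). CSN3, which encodes kappa-casein, was the most abundant gene in both, at 5.39% (5.37 to 5.40%) and 5.05% (5.04 to 5.06%). The other most abundant genes were CSN1S1, CSN2, the uncharacterised LOC101903787, the beta-lactoglobulin gene PAEP in HH, and the lactoferrin gene LTF in LL.

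The first comparison asked which genes differed between the HH and LL RNA-seq libraries. The lists of luminal, basal and stromal markers and of cholesterol synthesis genes had median ratios above those of random lists, and the lists of inflammation and host defence genes and of fatty acid oxidation genes had medians below them, although most members of each list were not past 2-fold. The medians of genes that make triacylglycerol or coat the fat globule lay inside the range of random lists. Most genes were close: the median log2 ratio was −0.01 with quartiles at −0.23 and 0.24. Of 12804 genes with at least 100 summed counts, 240 were higher in HH and 128 higher in LL with the whole interval past 2-fold, and 12436 were neither.

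Among genes with at least 100 summed counts and a name other than a LOC number, the highest in HH was PRSS2, a trypsinogen gene, with 808 counts against 0. Against the floor of 3 counts in the LL library this is a 245-fold ratio, with an exact lower bound of 199-fold. FUT6, a fucosyltransferase gene, had 250 counts against 1, a 227-fold ratio with a counting interval from 40.4- to 9012-fold. BDA20, a lipocalin gene, had 127 against 0, 38.5-fold against the floor (lower bound 30.85). RPL12, a ribosomal protein gene, followed at 27.6-fold (23.4 to 32.7), with 4426 counts against 146. LOC784762, annotated as its pseudogene and looked up after the values were seen, went the other way, with 205 against 5147, so the RPL12 ratio is uncertain; the 2 genes summed had a log2 ratio of −0.33. SBSPON, GPA33, TMEM176A, EXTL1, SERPINA11 and PTGR1 had log2 ratios from 3.18 to 4.44. EOMES, a transcription factor of T and natural killer cells, had 4.01 (2.84 to 5.48), and FOSB, a subunit of the AP-1 transcription factor, 2.91 (2.60 to 3.23).

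Under the same limit the named gene highest in LL was MKI67, the proliferation marker Ki-67, with 472 counts against 12, a log2 ratio of −5.44 (−6.40 to −4.62). LAP, an antimicrobial beta-defensin, had 200 counts against 6 (−5.20, interval −6.66 to −4.05). C4BPA, a regulator of the complement system, had 3561 against 273 (−3.84). SLC5A5, the sodium iodide symporter, was at −4.07. IGCGAMMA, an immunoglobulin gamma constant-region gene, had 79951 counts against 8124 (−3.44). M-SAA3.2, the mammary serum amyloid A gene, was at −2.60 and the ceruloplasmin gene CP at −2.65. IGSF9B, FRMPD3, PPP1R1B and ZG16B had log2 ratios between −4.30 and −2.90. PRSS2, FUT6, IGCGAMMA and M-SAA3.2 belong to families of similar genes, and how the counting treated reads shared between such copies is not given in the sources used here.

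**Figure D1:**
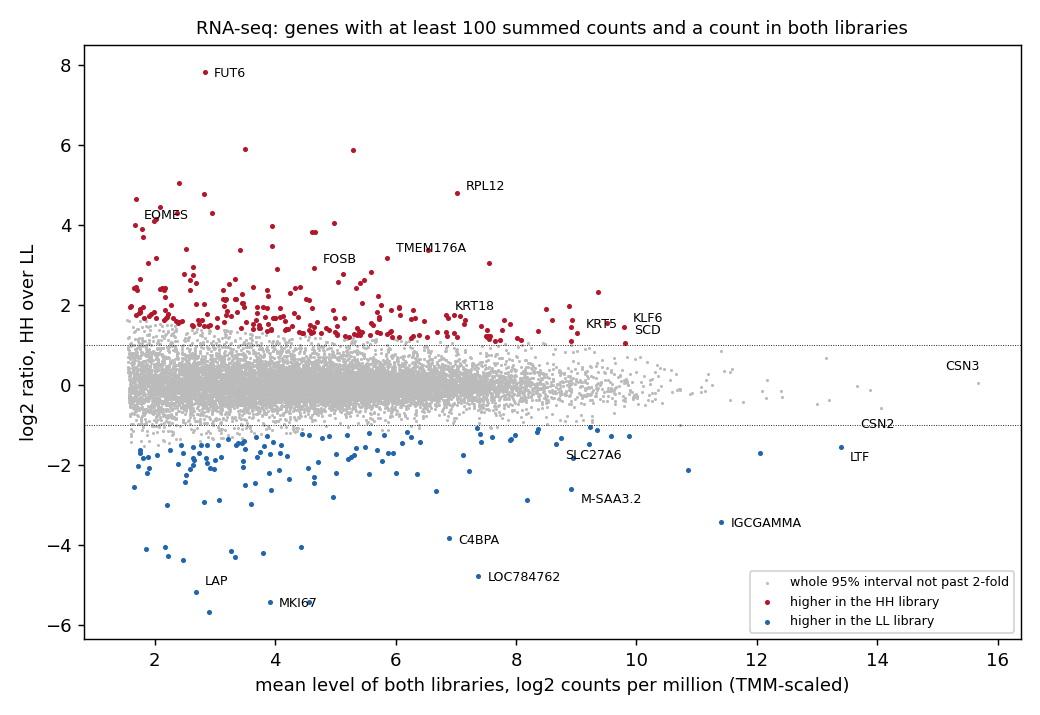
Log2 ratio of the HH over the LL RNA-seq library against the mean level of both in log2 CPM. CPM are here counts scaled to 1000000 of the TMM-scaled library total. Each point is 1 gene with at least 100 summed counts and a count in both libraries. Red points (higher in HH) and blue points (higher in LL) have their whole 95% counting interval past the dotted 2-fold lines; CSN3, at the far right, lies at a log2 ratio of 0.04.

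Groups of genes were compared through 23 lists fixed before the data were examined. Each list's median log2 ratio was set against 10000 random lists of the same size and similar mean expression, and the percentile describes these libraries only. Of the 22 lists with measured genes, 8 lay above the middle 95% of their random lists and 6 below it. Resampling the members gave medians on both sides of 0 for 5 of these, which stand apart less firmly: fatty acid uptake (−0.38 to 0.43), milk protein (−0.495 to 0.12), endothelial markers (−0.33 to 0.03), inflammation (−1.208 to 0.009) and immediate early genes (−0.01 to 0.91). Some other lists kept to the same side of 0 on resampling but reached into the range of their random lists. The interferon response went down to 0.10 and glycolysis to 0.08, with random lists up to 0.21 and 0.14. The cell cycle went up to −0.05 and fatty acid oxidation to −0.1495, with random lists from −0.24 and −0.152. These too stand apart less firmly. The list of mitochondrially encoded genes had no gene in the table.

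Genes of fatty acid synthesis had a median log2 ratio of 0.15, at percentile 96.6, and 1 of 25 measured members was past 2-fold. That member was SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, at 1.05 (1.01 to 1.08), and it was no longer past 2-fold under upper-quartile scaling (0.99 to 1.06). FASN, the fatty acid synthase, was at 0.36 and ACACA, which makes malonyl-CoA, at −0.20; FADS3, ELOVL6 and ACSS1 were at 1.04, 0.72 and −0.89. Fatty acid uptake and activation had a median of 0.18 at percentile 97.9, with 0 of 18 members past 2-fold in HH. The percentile was 94.0 when only members with at least 100 counts entered. One member, the fatty acid transporter SLC27A6, was past 2-fold in LL at −1.49 (−1.54 to −1.44). VLDLR was at 1.08, and LPL, CD36 and FABP3, which release, take up and bind fatty acids, were at 0.36, 0.25 and 0.54.

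Triacylglycerol synthesis genes had a median of −0.04 at percentile 40.4, and none of the 13 was past 2-fold. AGPAT2, an acyltransferase of this pathway, was at 1.16, GPAM at 0.30, LPIN1 at −0.52, DGAT1 at −0.06 and DGAT2 at −0.90 with 23 counts in HH and 39 in LL. Lipid droplet and milk fat globule genes had a median of −0.07 at percentile 31.2, with none of 15 past 2-fold. Among them BTN1A1, a protein of the fat globule membrane, was at 0.85, XDH at −0.38, PLIN2 at −0.24, CIDEA at 0.68 and PLIN3 at −0.58. Transcription regulators of lipid genes had a median of −0.07 at percentile 26.5, again with none of 17 past 2-fold. SREBF1, which encodes the sterol response factor of fatty acid synthesis, was at −0.75, and SREBF2, its counterpart for cholesterol, at 0.57. INSIG1 was at 0.63, MLXIPL at 0.89 and PPARG at 0.06.

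Cholesterol synthesis genes had a median of 0.38, above all random lists. Of its 21 measured members, the enzymes SQLE and CYP51A1 were at 0.99 and 0.95. Fatty acid oxidation and lipolysis lay on the other side, with a median of −0.29 at percentile 0.01. Its only member past 2-fold among 26 was ABHD5, a co-activator of fat breakdown, higher in LL at −1.92 (−2.30 to −1.56). CPT1A, an enzyme of fatty acid entry into mitochondria, was at −0.58 and ACAA1 at −0.66. In the same libraries the luminal, basal and stromal marker lists, given next, had medians from 0.30 to 0.63, and the endothelial, immune and adipocyte lists from −0.22 to 0.03.

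The luminal epithelial, basal and stromal marker lists each had a median above the middle 95% of their random lists. Luminal markers had a median of 0.30 at percentile 99.9, with KRT18 (1.74), CLDN4 (1.61) and CLDN3 (1.10) the 3 of 16 members past 2-fold; KRT8 and KRT19 were at 0.55 and 0.84. Basal and myoepithelial markers had a median of 0.60, above all random lists, with 5 of 18 past 2-fold, 4 under the upper quartile and 7 under total scaling. These included the keratins KRT14 (1.70), KRT17 (1.61) and KRT5 (1.29) and the laminin chain LAMB3 (1.19). Fibroblast and stromal markers had a median of 0.63, also above all random lists, with 1 of 24 past 2-fold, or 2 under total scaling. The 1 was the matrix metalloproteinase MMP2 at 1.51; LUM and FAP were at 1.23 and 1.25, and VIM at 0.16.

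Endothelial markers had a median of −0.22 at percentile 2.22, or 6.85 without matching on expression, and none of 10 was past 2-fold; VWF was at −0.44 and TIE1 at 0.43. Immune cell markers had a median of 0.03 at percentile 62.8, with none of 15 past 2-fold. CD3D and CD3E, of the T cell receptor complex, were at 1.22 and 1.02. Adipocyte markers, with 5 measured, had a median of 0.02 at percentile 55.7.

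Milk protein and lactose genes had a median of −0.25 at percentile 0.43. LTF was the 1 of 16 past 2-fold, at −1.56 (−1.57 to −1.54), and the antibacterial lactoperoxidase gene LPO was at −0.98. The prolactin receptor PRLR was at −0.63, CSN2 at −0.59, CSN3 at 0.04 and PAEP at 0.66. Ribosomal protein genes had a median of −0.20, below all random lists. The only 1 of 81 past 2-fold was RPL12, which went the other way at 4.78, a ratio called uncertain above.

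Inflammation and host defence genes had a median of −0.75, below all random lists. Of 20 members 6 were past 2-fold in LL (5 under total scaling), among them LAP, M-SAA3.2 and S100A9 (−2.05), a calcium-binding protein of neutrophils. The list also held 2 genes past 2-fold in HH, including CCL5, a chemokine made by T cells, at 2.04. Interferon response genes had a median of 0.74, above all random lists. Their 2 members past 2-fold of 24 were OAS1X at 2.41 (1.76 to 3.11) and IFI6 at 2.01 (1.52 to 2.54); ISG15 and IFI44 were at 1.14 and 1.13. OAS1X has close paralogs and had 134 counts in HH and 23 in LL.

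Cell cycle genes had a median of −0.33 at percentile 0.36, with 6 of 25 past 2-fold in LL (5 under total scaling) and none in HH. MKI67 was the only 1 of these among the 12 members with at least 100 counts, where the median was −0.06 at percentile 33.2. AURKA and MCM6 were at −0.42 and −0.33, and MCM4 at 0.31. Immediate early genes had a median of 0.37 at percentile 99.9, with FOSB and KLF6 (1.44) past 2-fold of 12. JUND was at 0.93. Glycolysis and hypoxia genes had a median of 0.29 at percentile 99.97, with 3 of 23 past 2-fold. These included ADM, a peptide hormone induced by low oxygen, at 1.91 and the glucose transporter SLC2A3 at 1.25.

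Insulin, AMPK and mTOR signalling genes had a median of 0.00 at percentile 61.9. IGFBP5, which binds insulin-like growth factors, was the 1 of 22 past 2-fold, at 1.58 (1.46 to 1.71); IGFBP6 and IRS2 were at 1.24 and 0.96. Unfolded protein and integrated stress response genes had a median of −0.02 at percentile 50.7. Here 2 of 16 were past 2-fold in opposite directions, the stress factor ATF3 at 2.61 (2.39 to 2.83) and SESN2 at −2.10 (−2.57 to −1.66).

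**Figure D2:**
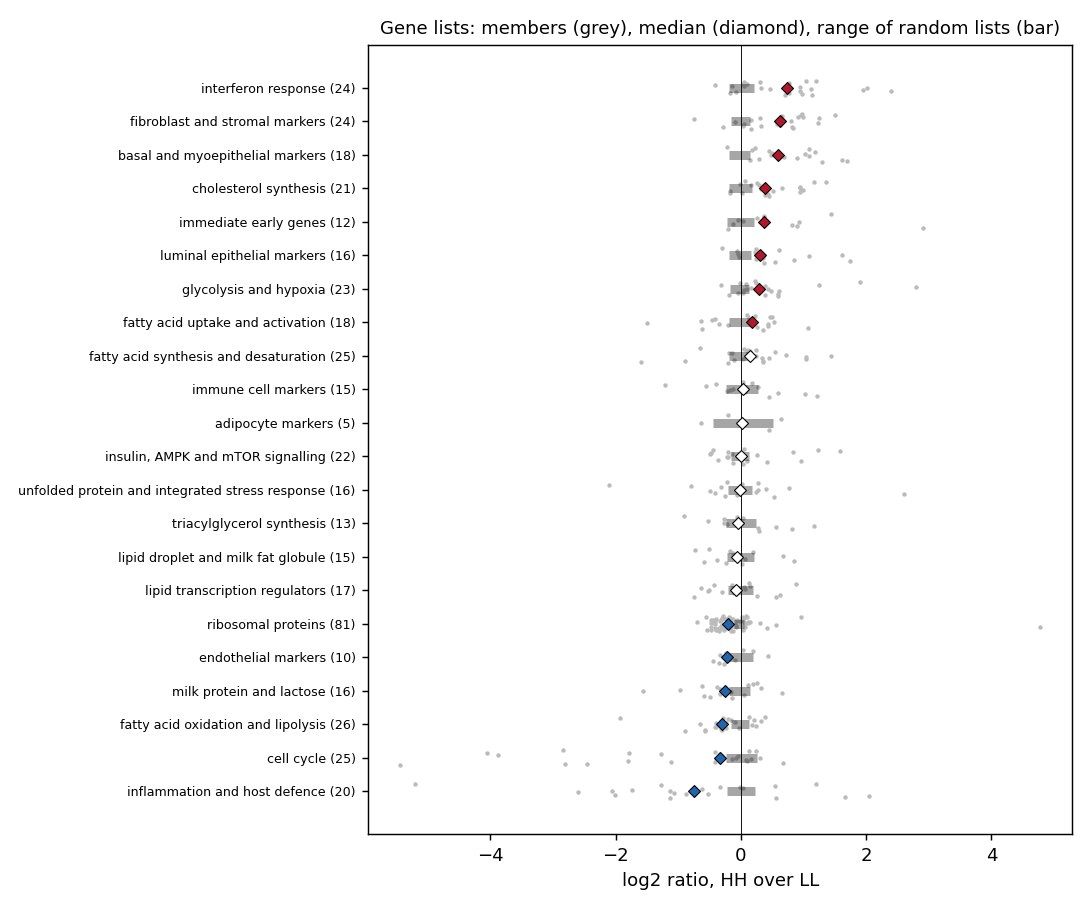
Log2 ratio of the HH over the LL RNA-seq library for the members of each fixed gene list (grey points, number measured in brackets), with the list's median (diamond) and the range holding the middle 95% of medians of random lists matched on expression (bar). Red diamonds lie above that range and blue ones below; the medians run from −0.75 for inflammation and host defence to 0.74 for the interferon response.

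The second comparison asked which miRNAs differed between the HH and LL small RNA libraries. The let-7 family made up 76.1% of the HH miRNA reads (exact interval 76.09 to 76.15%) and 58.7% of the LL reads (58.71 to 58.78%). Precursor bta-mir-222 made up 7.15% (7.13 to 7.17%) against 22.01% (21.98 to 22.04%). Among precursors with at least 100 summed reads the highest in HH was bta-mir-33a, which lies inside SREBF2 in the RefSeq table of ARS-UCD2.0, and those highest in LL included bta-mir-224 and bta-mir-452. Below that limit bta-mir-29b-2, singled out after its values were seen, had 99 reads in HH and 0 in LL, 40.6-fold higher in HH against the floor of 3 reads (exact lower bound 32.42). Of the 99 reads, 96 had the same sequence, which begins with the whole leading tag of bta-mir-29b-1. The value is therefore not separate from that of bta-mir-29b-1 and may depend on how reads were assigned. Of the 143 precursors within the limit, 24 were higher in HH and 16 higher in LL with the whole interval past 2-fold. Scaling moved this split: by the upper quartile it was 18 and 20, so that 47.4% of the calls were higher in HH in place of 60.0%.

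Under the main scaling the median precursor had a log2 ratio of 0.24. DESeq2 size factors shifted every ratio by −0.18 and upper-quartile scaling by −0.30, so the direction of a ratio inside that range depends on the scaling. Precursor bta-mir-33a had 291 reads in HH and 17 in LL, a log2 ratio of 4.40 (3.69 to 5.20). The other precursors highest in HH were bta-mir-152 (2.66), bta-mir-29b-1 (2.47), bta-mir-30b (2.52), bta-mir-342 (1.99), bta-mir-449a (2.31), bta-mir-145 (1.995) and bta-mir-196b (2.33). Precursor bta-mir-124b had 167 reads in LL and 0 in HH, 45.2-fold lower in HH against a floor of 3 reads in that library (exact bound 36.38). Next in LL came bta-mir-224 (−3.09), bta-mir-452 (−2.65), bta-mir-760 (−2.41), bta-mir-877 (−2.17), bta-mir-2344 (−2.11), bta-mir-92b (−1.75) and bta-mir-222 (−1.68, interval −1.68 to −1.67). The most abundant let-7 precursors, bta-let-7a-3 and bta-let-7b, were at 0.23 and 0.24, bta-let-7f-1 at 0.78, bta-let-7i at 0.62 and bta-mir-221 at −0.48.

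The ratios were lower for miRNAs richer in G and C. The median log2 ratio was 0.56 over the 47 precursors of lowest GC content and −0.24 over the 48 of highest. After a straight line on GC content was removed, an alternative chosen after seeing the data, 24 precursors were higher in HH, the same number as before. Those higher in LL numbered 9 in place of 16. Whether the same precursors were called was not compared. The 2 arms of a precursor also differed: they were at 2.15 and −0.40 in bta-mir-342, 2.53 and −1.26 in bta-mir-29b-1, and 3.42 and 0.47 in bta-mir-30b.

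**Figure D3:**
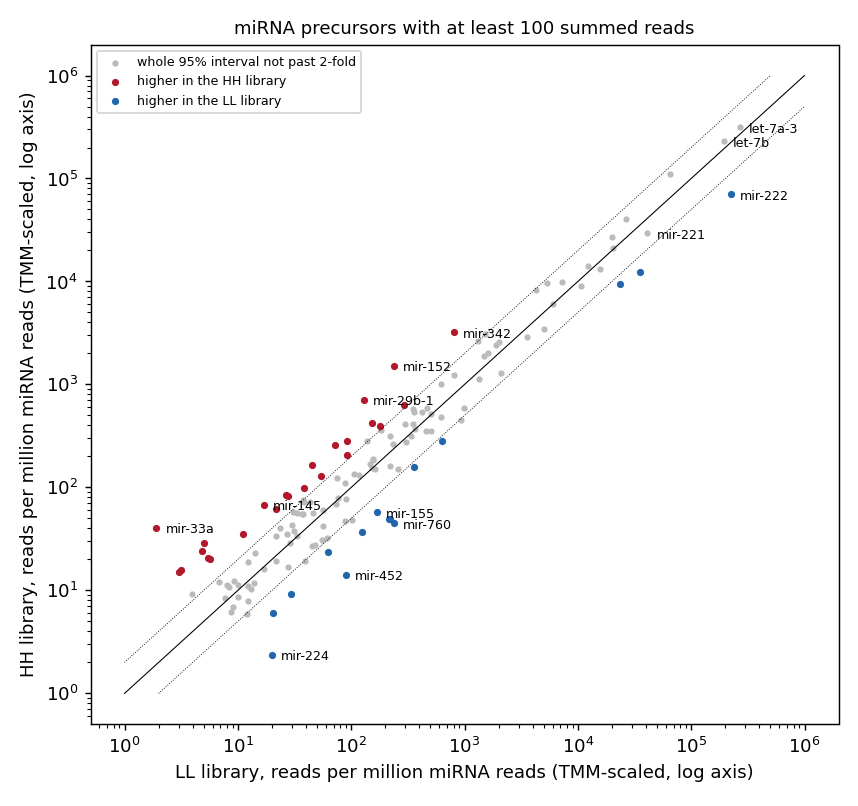
Level of each miRNA precursor in the HH library against the LL library, in RPM with TMM-scaled totals, on log axes. Shown are precursors with at least 100 summed reads and a read in both. The solid line marks equal levels and the dotted lines 2-fold; red points (higher in HH, such as mir-33a) and blue points (higher in LL, such as mir-222) have their whole 95% counting interval past 2-fold.

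**Figure D4:**
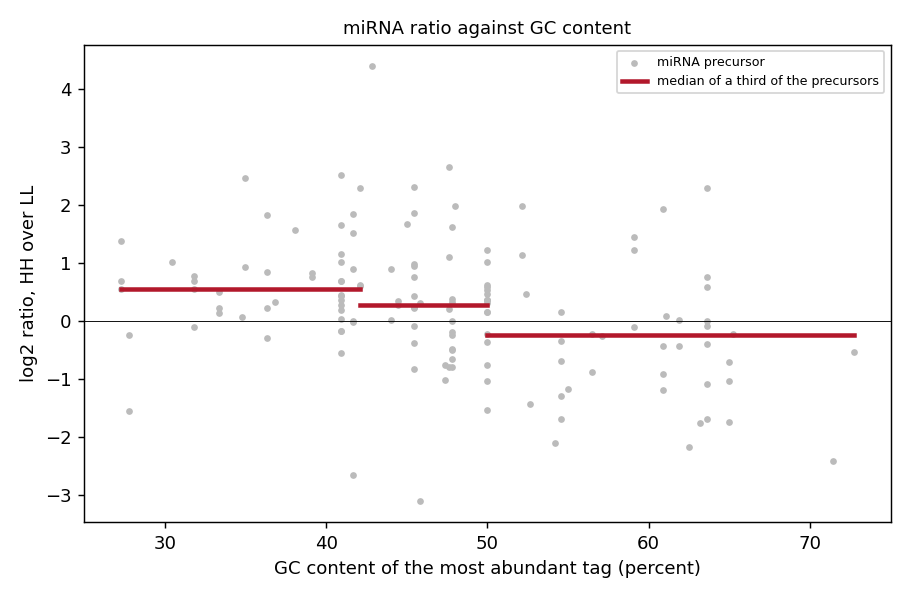
Log2 ratio of the HH over the LL small RNA library against the GC content of each precursor's most abundant tag, 1 point per precursor with at least 100 summed reads and a read in both libraries. Red lines are the medians of the precursors of lowest (0.56), middle (0.29) and highest (−0.24) GC content.

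Of 7 fixed miRNA lists, 5 had at least 3 measured precursors. The list of miRNAs tied to milk fat in earlier bovine and goat mammary work had a median log2 ratio of 0.69 at percentile 99.4 of random lists. Of its 31 measured precursors 8 were past 2-fold in HH, including bta-mir-33a, bta-mir-29b-1 and bta-mir-16b (1.87), and 1 in LL, bta-mir-224. Under DESeq2 size factors or the upper quartile 7 were past 2-fold in HH. Among the 8 were bta-mir-29b-1, bta-mir-29b-2 and bta-mir-29c, whose leading tags begin alike, as do those of bta-mir-15a, bta-mir-16a and bta-mir-16b. Of these, bta-mir-29b-1 and bta-mir-29b-2 are precursors of the same mature miRNA, and the others are related miRNAs with different tags. Members of such families are not independent of each other. The random lists were matched on mean expression only, not on such families. With the GC line removed the median of the list was 0.49 at percentile 98.6. Mesenchymal and smooth muscle miRNAs had a median of 0.51 at percentile 78.4, with bta-mir-143 (1.11), bta-mir-145 and bta-mir-214 (1.23) the 3 of 10 past 2-fold; under DESeq2 size factors or the upper quartile only bta-mir-145 was. Endothelial and blood cell miRNAs had 3 measured precursors, which went both ways, among them bta-mir-146b at 1.86 and bta-mir-155 at −1.55. Their median of 1.855 was at the upper limit of the random lists (1.855, percentile 97.6), and resampling the members gave −1.545 to 2.69, so with 3 members the list did not clearly stand apart. The percentile was 94.5 with the GC line removed. The let-7 family had a median of 0.24 at percentile 46.6 and none of 11 past 2-fold, or 1 under total scaling. The miR-17-92 group had a median of 0.15 at percentile 43.9, with bta-mir-93 at 1.14 and bta-mir-92a at −1.17 past 2-fold of 8, the former not under DESeq2 size factors or the upper quartile.

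Epithelial miRNAs, such as the miR-200 family, miR-205 and miR-203, were near 0. The 10 names of that list had 2 reads together in HH and 3 in LL, where the floor of 3 reads is 0.423 and 0.331 RPM (reads scaled to 1000000 miRNA reads). The 39 names of the imprinted DLK1-DIO3 cluster had 3 and 83 reads.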

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

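The tests on annotation, on cells differing between library types, and on the named gene copies were chosen after the result was seen; those on the arms, on short tags, on GC-poor losses and on copies in general were set before their values were computed. The arm and short-tag tests were set after the GC trend had been seen, in place of earlier ones that could not decide, the trend itself and tags of at least 21 nt. The main comparison summed tags of 18 to 29 nt and did not use their length. Tags of 18 to 20 nt made up 19% of the LL miRNA reads (exact interval 18.97 to 19.03%) against 6.85% in HH, and their share was higher in LL for 72 of the 83 precursors with at least 1000 reads. In bta-let-7b the 19 nt tag TGAGGTAGTAGGTTGTGTG held 44.2% of the LL reads and 8.34% of the HH reads.

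Across 142 precursors the miRNA log2 ratio went down with the GC content of the leading tag (Spearman's rho −0.39, permutation p = 2e-05, adjusted 0.0001; Pearson's r −0.33, p = 8e-05, adjusted 0.0004; precursors are not independent replicates). Without the 2 precursors of most extreme GC content, r was −0.30. Over tags of at least 21 nt alone, 133 precursors had a Spearman's rho of −0.35 (permutation p = 7e-05, adjusted 0.00017). Reads shortened below 21 nt drop out of that set, so this value cannot decide on a loss of 3′ ends. Loss of 3′ ends in LL stays open as the source. It would need GC-poor precursors to be shortened more in LL, and over 83 precursors GC content and the share of tags of 18 to 20 nt in LL minus HH had a rho of −0.077 (permutation p = 0.49, adjusted 0.53), too weak to decide. A GC bias between the library preparations also stays open. Within 74 precursors the difference between arms in GC went with their difference in ratio at rho −0.19 (permutation p = 0.10, adjusted 0.20), too weak to decide. Where a miRNA has several precursors, the arms listed under a single precursor may not come from the same transcript. A difference between the HH and LL cells stays open too and was not tested, because each code has 1 library.

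The 10 epithelial miRNAs and most of the 9 endothelial and blood cell miRNAs were near 0, with miR-155 (58.7 RPM in HH and 164.9 in LL) and miR-146b (20.7 and 5.52 RPM) as exceptions, although the RNA-seq libraries held abundant caseins and keratins, 4183 and 4571 counts of the endothelial gene PECAM1, and 822 and 545 of the leukocyte gene PTPRC, both picked after their values were seen. Of the 15 such miRNAs under 10 reads per library, 9 had a tag, so annotation did not leave those out; for the 6 without a tag this stays open. A loss of GC-poor small RNAs is hard to reconcile with 12 precursors of equally low GC content above 100 RPM in both libraries, although only 2 of the 10 most abundant were that low. That the RNA-seq and small RNA libraries may hold different cells stays open: no epithelial miRNA exceeded 0.141 RPM, but only 5 of 10 mesenchymal miRNAs were above 100 RPM in both libraries.

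Some of the most extreme RNA-seq ratios sat in related gene copies going opposite ways. RPL12 and LOC784762 had log2 ratios of 4.78 and −4.79, and their summed counts −0.33, which is consistent with reads of a single gene being split differently between the copies. For the 5 genes most similar to ABCC4 the summed counts still had a log2 ratio of 2.26 (2.13 to 2.39). A split alone thus does not account for their ratios, but the sum cannot tell whether reads were also split within the family. Of 83 genes past 4-fold, 3.61% had an opposite partner with the same human match, above random gene sets matched on expression (median 0.0%, upper limit 1.205%). All 3 of these genes are ABCC4-like, so the excess comes from that family alone and does not show a split. Only 51.8% of the 83 have a human match, so for the rest a split stays open too. Haplotype differences between the animals stay open and were not tested.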

How the results depend on the processing

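The alternatives on GC content, tag length, arm, shared human matches and gene type were chosen after seeing the data. Over all alternatives run, no gene count, list or named feature reversed its direction as a call. For the scalings this was fixed in advance. Their largest shifts in log2 were 0.047 for genes (total scaling) and −0.30 for miRNAs (upper quartile), too small to reverse a call past 2-fold. The balance of miRNA calls did turn, from 24 higher in HH and 16 in LL to 18 and 20 under the upper quartile. RNA-seq counts stayed within 1.5 times of 240 and 128 under every scaling, without genes sharing a human match, and with mRNA genes only. Genes higher in HH and in LL numbered 137 and 66 with at least 500 counts, 452 and 229 by the point ratio, and 49 and 34 past 4-fold; without a filter 218 were higher in LL. The wider or narrower definition itself sets these. For miRNAs, 4 and 5 were past 4-fold, and with the GC line removed 24 were higher in HH and 9 in LL. Among all miRNA values under the alternatives, 19 stayed within 1.5 times, including the 24 with the GC line removed.

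Among list medians 4 gene list values and 1 miRNA list value lost their place outside the middle 95% of the random lists. Another 84 and 18 stayed on the same side of these limits, but these include the changes of scaling. A change of scaling shifts a list and its random lists alike, so it could not move a percentile and is no check of it. Some medians inside the limits changed sign. Triacylglycerol synthesis, at −0.04, had 0.0043 under total scaling and 0.0353 with at least 100 counts. The stress response list, at −0.02, had 0.0301 and 0.0238, and adipocyte markers, at 0.02, had −0.0944 with at least 100 counts. The miR-17-92 group, at 0.15, had −0.0308 under DESeq2 size factors but 0.5071 (percentile 76.1) with at least 100 counts and 0.4765 (percentile 79.4) with the GC line removed, and the let-7 family, at 0.24, had −0.0031 with the GC line removed. Fatty acid uptake fell back to a median of 0.13 (percentile 94.0) with at least 100 counts and stayed at 0.18 (percentile 94.99) against unmatched lists. Endothelial markers, at −0.22, had percentile 6.85 against unmatched lists. The cell cycle list had −0.0635 (percentile 33.2) with at least 100 counts, where low-count genes drop out. Endothelial and blood cell miRNAs, whose main median of 1.855 was at the upper limit itself, had 1.66 (percentile 94.5) with the GC line removed. Beyond what is said here, the cause was not tested.

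Of 156 named features, the value left its own counting interval in 27 under DESeq2 size factors, 28 under total scaling and 32 under the upper quartile. Seed-site comparisons with 8mer sites, 500 counts or other matching were not run. No paired analysis was possible because each code has 1 library per kind. Depth limits what is said of genes and miRNAs near 3 counts, where a difference was not detectable.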

Other observations

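The lists of plasma cell and T cell genes were chosen after the result was seen, from genes such as IGCGAMMA and EOMES, so they are not independent of it. Plasma cell genes had a median log2 ratio of −0.91 over 17 measured genes, and 5 were past 2-fold, or 4 under total scaling or DESeq2 size factors, where POU2AF1 fell inside, and 6 under the upper quartile. They included MZB1 (−2.35), which helps antibody secretion, the transcription factor IRF4 (−1.96), POU2AF1 (−1.31) and the immunoglobulin gene IGHG1 (−1.71). IGHG1 and IGCGAMMA together took 1.13% of the LL counts and 0.249% of the HH counts. The immunoglobulin genes IGHM and IGHE went the other way, at 0.67 and 0.39, as did SDC1, which epithelium also expresses, at 0.74, and JCHAIN, which joins antibody units, at 0.15 with 3359 counts in HH and 2758 in LL. PRDM1 was at −0.27.

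T and natural killer cell genes had a median of 0.69 over 23 measured genes, and 4 were past 2-fold. Those were EOMES (4.01), CCL5 (2.04), CD5 (1.82) and IL7R (1.56). The list shares 5 genes with the fixed lists, and the measured genes CD7 (−0.89), CD3G (−0.35), NKG7 (−0.09) and CD96 (−0.06) lay below 0, with CD8A at 0.07. The general immune list, fixed before the data were examined, stood at 0.03.

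Both arms of a miRNA precursor often differed in ratio. Over 74 precursors with at least 20 reads of each arm, the median absolute difference between arms was 1.13 in log2. Tags not sharing 12 bases with the most abundant tag were taken as the other arm, so some pairs may not be true arms. In bta-mir-2904-3 the tags of the pair overlap by a shorter stretch. In 43 of the 74 the intervals of the arms, which cover counting error only, did not overlap. Variation between preparations and animals has no estimate here, since each code has 1 library. Precursors bta-mir-23a, bta-mir-23b, bta-mir-25 and bta-mir-1271 had both arms past 2-fold in opposite directions, and in bta-mir-23b they were at 1.21 and −1.73. These precursors were singled out after their values were seen.

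A hypothesis set before its test was that a miRNA inside a gene shares that gene's ratio through joint transcription. Over 61 miRNAs in 51 genes the log2 ratios of miRNA and host had a Spearman's rho of 0.10 (permutation p = 0.44, adjusted 0.53) and a Pearson's r of 0.09 (p = 0.49, adjusted 0.49), across miRNAs that are not independent replicates. Without the 2 most extreme hosts r was 0.17. The relation was not detectable, and a weak one may still exist at rho 0.10. Where a miRNA has several precursors, most of its reads can be listed under a single precursor. In HH bta-let-7a-3 had 2273818 reads and bta-let-7a-1 had 2278. For such miRNAs the host taken here may not be the source of the reads. The pair bta-mir-33a and SREBF2 had log2 ratios of 4.40 and 0.57.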
